A study of Mus musculus with 22 samples.

How the data were processed

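RNA was measured in 22 libraries of microglia, the resident macrophages of the brain, collected by flow cytometry as cells positive for Cx3cr1 and CD45 from 7-week-old mice of the BALB/c strain. Npc1 encodes a membrane protein of late endosomes and lysosomes that moves cholesterol out of these compartments, and its loss causes Niemann-Pick disease type C. The mice were wild type (WT) or Npc1 knockout (KO). They were untreated, given phosphate-buffered saline (PBS) as vehicle, or given 4000 mg/kg of hydroxypropyl-beta-cyclodextrin (HPBCD), a ring-shaped sugar that binds cholesterol. There were 5 untreated libraries of each genotype and 3 libraries in each of the other 4 groups. RNA was purified with a column kit for small samples after storage in Trizol, and libraries came from a Clontech kit for picogram inputs, per the labels' protocols.

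The authors deposited read counts per gene in a sheet for the 12 libraries of treated mice, and a separate sheet for the 10 libraries of untreated mice. Per the file headers, both were made with featureCounts 1.4.6-p3 on a UCSC mm10 gene annotation with default options, so strand was not used and exons were summed per gene. The count commands named 21 alignments for the treated sheet and 10 for the untreated sheet, per the file headers. STAR 2.5.1 is named in the submitters' processing notes, and mm10 is their genome build. The authors' untreated sheet was handled as deposited, as an expected count per gene, because its last 2 lines, which name no gene and hold column totals, are not all whole numbers. Those lines were dropped and the gene values, already whole, were rounded without change. Because PBS and untreated libraries sit in sheets counted separately, any comparison between them cannot be told apart from a difference between the sheets. The authors also deposited tables of their own comparisons with log2 fold changes and p-values adjusted for multiple tests; the samples in those fits are not given in the sources used here.

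The sheets were joined by gene symbol into 24421 genes, of which 1 (Satb1) was matched by identical coordinates. The 3 WT PBS columns share a single name, so they carry no replicate number and are called a, b and c here. No pair of count columns was identical (0 found). Genes encoded by mitochondrial DNA were fixed as a list but had no measured member. Total counts ran from 18595411 to 38698910 per library. Unstranded counting cannot separate a gene from an antisense neighbour, and default counting leaves out reads that match several places, so values for genes with near-identical copies, such as ribosomal protein, H2 and histone genes, are uncertain.

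Comparisons used edgeR 4.0.16 in R 4.3.3, with TMM scaling, its low-count filter by group and the robust quasi-likelihood test with 1 mean per group. All 22 libraries entered a single fit and shared an estimate of the spread. This left 16992 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with standard errors (SE), and counts per 10⁶ counts (CPM) as mean ± SD with n libraries. The contrasts were KO against WT without treatment, with PBS and with HPBCD, HPBCD against PBS and PBS against untreated in each genotype, and 2 differences of differences. In 200 simulated changed genes, tested on simulated data from the real means, the procedure recovered 45% of 2-fold and 62% of 4-fold changes in the untreated genotype comparison, among 16504 genes with 4 wrong calls. Recovery was 35% and 60% for the PBS genotype comparison (16464 genes, 4 wrong calls), and 22% and 58% for HPBCD against PBS in KO (16498 genes, 3 wrong calls).

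Named genes followed a rule fixed before the data were examined, as were the contrasts, the gene lists and the other processing settings. Npc1 came first. For each main contrast the rule took the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between the 2 groups, then up to 4 called members of each list by adjusted p, or up to 2 uncalled members as values. For the differences of differences it took 5 each way. Provisional symbols (Gm, LOC, AI or BC with digits, or ending in Rik), Xist and Y-linked genes were left out of the largest changes and counted instead. C77080 is an expressed-sequence symbol of another form, which that rule did not cover, and it stayed in. The lists were disease-associated microglia, homeostatic microglia, cholesterol synthesis, LXR (liver X receptor) targets, fatty acid synthesis, lysosome, inflammatory cytokines with NF-kB targets, interferon response, antigen presentation, complement and phagocytosis, proliferation, glycolysis, oxidative phosphorylation, unfolded protein response, immediate early genes, cytosolic ribosome, and markers of neurons, astrocytes, oligodendrocytes, endothelial and mural cells, border macrophages, monocytes, neutrophils, T and NK cells, B cells and erythroid cells. The disease-associated and homeostatic lists came from general knowledge of microglia, not from these libraries.

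Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 26 lists. Camera compares a list with all other genes; an estimated correlation in its place is much stricter. The fry test asked whether a set moved, on balance, one way. Its p-values for the lists were adjusted over the 26 lists as well. Genes called between untreated KO and WT formed a signature, whose median change was followed in the 12 treated libraries. These shared the low-count filter and the spread of the fit that chose it. In the setting with only the groups of a contrast, the signature came from the untreated libraries alone. Alternatives were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, limma voom with sample quality weights, no low-count filter, only genes with a mean of at least 10 CPM, only the groups of a contrast, a block for replicate number, a term for the share of male RNA, list members shared with other lists left out, and each library left out in turn. Leaving out WT HPBCD replicate 3 and untreated KO replicate 5 together, the libraries with counts on many more genes than the rest, was chosen after seeing the data. The labels do not say that each library came from a separate animal, and 4 of the 22 libraries held both Xist and Y-linked counts. The p-values thus measure the spread between these libraries, which may be technical in part. Untreated WT replicates 1, 3 and 4 and untreated KO replicate 5 held Y-linked counts with almost no Xist. Untreated WT replicate 5 and untreated KO replicates 1, 2 and 4 held Xist with almost no Y-linked counts. With HPBCD, WT replicate 1 and KO replicate 2 were of the first kind, and KO replicates 1 and 3 of the second. Genotype and sex thus partly went together.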

Results

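Messenger RNA was counted in sorted microglia of WT and Npc1 KO mice at 7 weeks of age, without treatment or after PBS or HPBCD at 4000 mg/kg. Each untreated genotype had 5 libraries, and each genotype given PBS or HPBCD had 3. Total counts per library were 24278564 to 25550782 in untreated WT and 18595411 to 29489438 in untreated KO. They were 26159590 to 29187924 in WT and 33509229 to 38698910 in KO with PBS, and 23809911 to 32585332 in WT and 30280000 to 33302245 in KO with HPBCD. At least 10 counts were found on 12650 to 14477 genes in 20 libraries, on 18882 genes in untreated KO replicate 5 and on 21853 genes in WT HPBCD replicate 3. These 2 libraries are named below beside the gene groups they move.

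**Figure D1:**
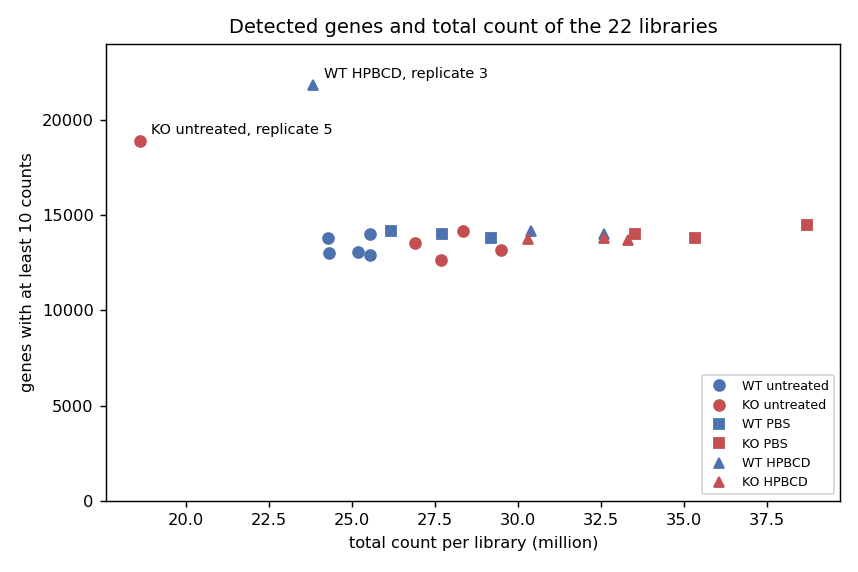
Genes with at least 10 counts (vertical axis) against the total count (horizontal axis) for the 22 libraries, coloured by genotype with a marker shape per treatment. WT HPBCD replicate 3 (21853 genes) and untreated KO replicate 5 (18882 genes) lie above the other 20 libraries (12650 to 14477 genes) at totals of 23809911 and 18595411 counts.

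Npc1 itself, on chromosome 18 at 12189694 to 12236386 of mm10, was measured first as the targeted gene. It stood at 434 ± 31.7 CPM in untreated WT and 44.5 ± 13.4 CPM in untreated KO (SD, n = 5 each). It was 273 ± 84.1 and 62.4 ± 9.41 CPM in WT and KO with PBS, and 426 ± 24.9 and 95.4 ± 5.11 CPM in WT and KO with HPBCD (SD, n = 3 each). Npc1 was 9.77-fold lower in untreated KO than in WT (log2 fold change −3.29, SE 0.16, adjusted p = 6.76e-15). The log2 differences with PBS and with HPBCD were −2.05 (SE 0.20, adjusted p = 2.14e-08) and −2.07 (SE 0.20, adjusted p = 4.74e-07). Every KO library lay below every WT library, so the labels and this transcript go together. The counts do not show which part of the gene was disrupted.

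**Figure D2:**
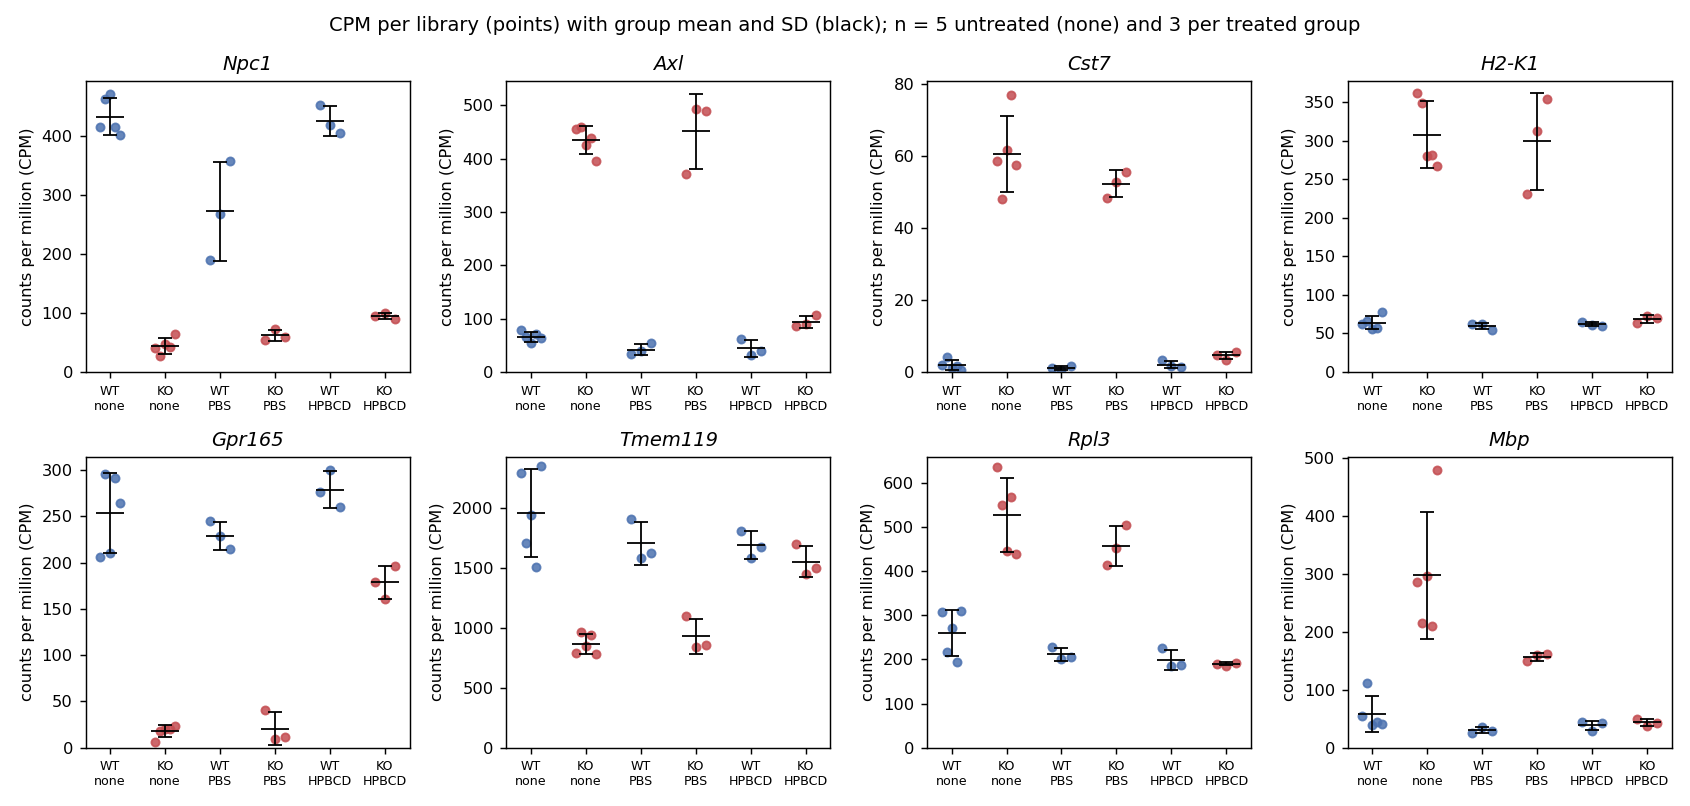
CPM per library (points) for Npc1, Axl, Cst7, H2-K1, Gpr165, Tmem119, Rpl3 and Mbp in the 6 groups, with group mean and SD in black; n = 5 for untreated (none) and 3 for the other groups. In KO, Axl averaged 435 CPM without treatment, 451 CPM with PBS and 94.3 CPM with HPBCD, and Gpr165 17.7, 20.7 and 179 CPM.

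The first comparison asks how microglia without Npc1 differ from WT when untreated. KO microglia gained genes of the disease-associated state, which microglia enter around lipid and debris. Apoe, a lipid carrier, rose from 5651 ± 670 to 30790 ± 5350 CPM (SD, n = 5). Its log2 fold change was 2.47 (SE 0.17, adjusted p = 5.81e-12). Axl, a receptor for dying cells, rose from 66.4 ± 9.24 to 435 ± 25.7 CPM (2.73, SE 0.17, adjusted p = 3.79e-12). Itgax, the integrin CD11c, rose by 2.02 and the lysosomal protease Ctsb by 1.82 on the log2 scale. Of the 40 genes of the list, 34 rose and 0 fell (36 rose adjusted over the list alone). The list passed with an estimated correlation as well (camera adjusted p = 1.76e-31, and adjusted p = 0.00611 with an estimated correlation). The homeostatic list of genes that mark resting microglia moved the other way, with 25 of 34 members lower and 3 higher (30 and 4 adjusted over the list alone; camera adjusted p = 6.44e-14, adjusted p = 0.0733 with an estimated correlation). Among them Tmem119, a microglial surface marker, fell from 1959 ± 365 to 867 ± 84.8 CPM (−1.17, SE 0.14). Selplg, a ligand of P-selectin, fell by 1.72 and the fructose transporter Slc2a5 by 2.48 on the log2 scale.

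In all, 1788 genes were higher and 1621 lower in untreated KO, 890 and 350 of them by more than 2-fold. The counts were 2450 and 1771 with the DESeq2 Wald test, 1508 and 1110 with limma voom, and 1265 and 986 with only the untreated libraries. With a term for the share of male RNA they were 1613 and 1487. The largest rises included Lox, which crosslinks collagen (log2 fold change 5.27, SE 0.60), Cst7, an inhibitor of lysosomal proteases (5.05, SE 0.42), the sulfotransferase Chst2 (4.97, SE 0.36), the heparan sulfate-cleaving enzyme Hpse (4.55, SE 0.47), the glutathione peroxidase Gpx3 (4.5, SE 0.55), the fatty acid-binding protein Fabp5 (4.32, SE 0.60) and C77080 (4.25, SE 0.67). Cst7 went from 1.88 ± 1.44 to 60.5 ± 10.5 CPM (SD, n = 5). The largest falls were Gpr165, an orphan receptor (−3.83, SE 0.37), Npc1 itself (−3.29), Cass4 (−3.27), the chemokine receptor Ccr1 (−3.12), the secreted protein Serpinf1 (−3.11), the prostaglandin-degrading enzyme Hpgd (−3.10), the lipid flippase Atp8b1 (−3.05) and Trp53i11 (−2.99). The naming rule admitted only genes for which all 5 KO libraries lay on one side of all 5 WT libraries. Adjusted p ran up to 0.000123 for C77080. The called genes also held 147 with provisional symbols. The authors' deposited table listed 2900 genes with an adjusted p under 0.05, and 2676 of them were called here in the same direction.

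By camera 15 of the 26 lists were higher and 2 lower in untreated KO, and 1, the disease-associated list, passed with an estimated correlation. By fry 18 were higher and 1 lower. The interferon response list had 22 of 28 members higher and 0 lower (25 higher adjusted over the list alone; camera adjusted p = 1.64e-16, adjusted p = 0.0733 with an estimated correlation). It included Lgals3bp (2.44, SE 0.16), Rtp4 (2.82, SE 0.31), Ifit2 (2.37, SE 0.28) and Ifi44 (2.03, SE 0.22). The antigen presentation list counted 5 higher and 2 lower of 18 (6 and 2 adjusted over the list alone; camera adjusted p = 0.00977, adjusted p = 0.359 with an estimated correlation). Of its members H2-K1 rose from 64.1 ± 8.89 to 308 ± 43.7 CPM (2.29, SE 0.14), H2-D1 by 2.76, Nlrc5 by 2.55 and B2m by 1.10 on the log2 scale. Of 32 inflammatory cytokine and NF-kB genes, 11 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.00611, adjusted p = 0.272 with an estimated correlation). Il1b rose from 9.68 ± 3.30 to 49.4 ± 3.71 CPM (2.38, SE 0.23), with Cxcl16 up by 1.10, Il1rn by 4.11 and Cxcl10 by 4.90. The complement and phagocytosis list had 12 higher and 5 lower of 25 (13 and 5 adjusted over the list alone; camera adjusted p = 0.0121, adjusted p = 0.36 with an estimated correlation). Within it the complement receptor C3ar1 rose by 1.02, while Elmo1 and the Fc receptor Fcgr1 fell by 0.80 and by 0.81. This list no longer passed without untreated KO replicate 4 (adjusted p = 0.0504).

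Of 49 lysosomal genes, 29 rose and 2 fell in untreated KO (30 and 5 adjusted over the list alone; camera adjusted p = 1.1e-10, adjusted p = 0.293 with an estimated correlation), including the tetraspanin Cd63 (2.31, SE 0.16), the proton pump subunit Atp6v1a (1.59, SE 0.14) and the cholesterol carrier Npc2 (1.32, SE 0.14). The cholesterol synthesis and uptake list had 5 higher and 0 lower of 25 (6 higher adjusted over the list alone; camera adjusted p = 0.00712, adjusted p = 0.16 with an estimated correlation). They included Srebf2, the regulator of sterol synthesis (0.94, SE 0.15), Mvd (1.37, SE 0.24) and Hmgcs1 (0.73, SE 0.15). Of 14 LXR targets 5 rose and 2 fell, and the list did not pass (5 and 2 adjusted over the list alone; camera adjusted p = 0.0542). Smpdl3a (1.24) and Plin2 (0.80) rose and Mylip (−0.39) fell. For fatty acid synthesis 2 of 13 rose, Acaca (0.69, SE 0.18) and Scd1 (1.35, SE 0.43), and the list did not pass (2 adjusted over the list alone; camera adjusted p = 0.207). Scd1 missed the threshold without untreated KO replicate 5 (adjusted p = 0.113) or untreated WT replicates 1, 3, 4 or 5 (0.0545, 0.0693, 0.0722 and 0.0615).

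The cytosolic ribosome list had 37 of 39 members higher in untreated KO (37 adjusted over the list alone; camera adjusted p = 2.09e-16, adjusted p = 0.273 with an estimated correlation), with Rpl3 at 528 ± 84.2 CPM against 261 ± 52.7 (SD, n = 5; 1.03, SE 0.15), Rps19 up by 1.14 and Rpl4 by 0.95. Of 18 glycolysis genes 12 rose (12 adjusted over the list alone; camera adjusted p = 6.46e-09, adjusted p = 0.0733 with an estimated correlation), including Pkm (1.43), Aldoa (1.41), Pgam1 (1.35) and Ldha (1.05). Oxidative phosphorylation had 12 of 33 higher (15 adjusted over the list alone; camera adjusted p = 1.23e-05, adjusted p = 0.36 with an estimated correlation), with Cox5b up by 0.87 and Ndufb9 by 0.79. Proliferation had 8 of 28 higher (8 adjusted over the list alone; camera adjusted p = 6.7e-05, adjusted p = 0.0733 with an estimated correlation), among them the replication helicase genes Mcm2 (1.10) and Mcm3 (0.94) and the cycling marker Mki67 (1.22). The unfolded protein response list did not pass, with 2 higher, Canx (0.38) among them, and 3 lower, Pdia6 (−0.51) and Creld2 (−0.78) among them, of 21 (3 and 3 adjusted over the list alone; camera adjusted p = 0.182). Its median of −0.21 and the camera direction were down and its mean of 0.24 was up. Immediate early genes, which can be induced while tissue is dissociated, fell in 7 of 26 (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000104, adjusted p = 0.384 with an estimated correlation). Rhob fell by 1.10, Ier5 by 1.12, Btg2 by 1.47 and Ier2 by 1.83 on the log2 scale.

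Single transcripts known from other cells were also higher in untreated KO. The myelin gene Mbp rose from 58.4 ± 30.6 to 298 ± 109 CPM (SD, n = 5; 2.36, SE 0.24), Mobp by 3.21 and the astrocyte gene Gfap from 0.688 ± 0.341 to 45.1 ± 31.8 CPM (5.99, SE 0.81). The oligodendrocyte list had 3 of 13 higher (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0542) and the astrocyte list 3 of 12 (4 adjusted over the list alone; camera adjusted p = 0.104), so neither list passed. Neuronal genes rose in 6 of 16 (7 adjusted over the list alone; camera adjusted p = 0.000447, adjusted p = 0.302 with an estimated correlation), with Snap25 from 3.44 ± 1.90 to 13.1 ± 3.69 CPM (1.93, SE 0.49). Monocyte markers rose in 7 of 12 (8 adjusted over the list alone; camera adjusted p = 0.00082, adjusted p = 0.272 with an estimated correlation), led by Spn (2.11, SE 0.36) and Ace (2.33, SE 0.53). Neutrophil markers had 1 of 12 higher, Camp (1 adjusted over the list alone; camera adjusted p = 0.027, adjusted p = 0.293 with an estimated correlation), and this list missed the threshold without untreated WT replicate 4 (adjusted p = 0.0501) or untreated KO replicate 2 (adjusted p = 0.0623). Camp itself missed it without untreated KO replicate 2 (0.064) or untreated WT replicates 1, 2, 4 or 5 (0.0508, 0.0551, 0.0565 and 0.0523). Cd22, a receptor that B cells and some microglia carry, rose from 5.69 ± 1.49 to 90.5 ± 8.87 CPM (4, SE 0.20, adjusted p = 6.76e-15) and was the 1 called gene among 7 B cell markers (1 adjusted over the list alone; camera adjusted p = 0.0427, adjusted p = 0.302 with an estimated correlation). The B cell list did not pass without untreated KO replicates 3 or 5 (adjusted p = 0.116 and 0.101) or untreated WT replicates 1 or 5 (0.0853 and 0.0569), nor without both libraries with counts on many genes (0.0855). Border macrophage markers had 2 of 11 higher (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.442). These were Ms4a7, which missed the threshold without untreated WT replicates 2 or 3 (adjusted p = 0.0544 and 0.0512), and Clec12a, which missed it in 9 of 10 refits without 1 library (0.0517 to 0.104). Endothelial and mural markers had 1 higher and 1 lower of 11, Flt1 (3.45) and Pecam1 (−1.29; 1 and 1 adjusted over the list alone; camera adjusted p = 0.777). The endothelial list had a median of −0.13, a mean of 0.41 and a camera direction down. None of the 14 T and NK cell or the 4 erythroid markers was called by edgeR (0 of each, and 0 adjusted over the list alone; camera adjusted p = 0.579 and 0.423). Untreated KO replicate 5, 1 of the 2 libraries with counts on many genes, belongs to this group, and without both of them Mbp still rose by 2.19 (adjusted p = 1.7e-06), Gfap by 5.55 and Mobp by 3.03, while Aldoc lost its call (1.27, adjusted p = 0.0684), as it did without untreated WT replicate 3 (adjusted p = 0.0696) or untreated KO replicate 5 (0.0595).

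With PBS the same question was put to separate libraries, and 1191 genes were higher and 711 lower in KO than in WT. The counts were 1486 and 1135 with the DESeq2 Wald test, 2104 and 1737 with limma voom, and 1840 and 1347 with only the 6 libraries compared. With a term for the share of male RNA they were 1196 and 699. Apoe stood at 31960 ± 7260 CPM in KO against 4012 ± 877 in WT (SD, n = 3; 3.07, SE 0.23, adjusted p = 6.65e-11), and Axl at 451 ± 69.8 against 42.0 ± 10.8 CPM (3.50, SE 0.23, adjusted p = 3e-11). The largest rises were Hpse (7.05, SE 0.72), Cst7 (5.58, SE 0.56), Gfap (5.56, SE 1.04), Chst2 (5.47, SE 0.47), Gpx3 (5.32, SE 0.75), Lox (5.29, SE 0.78), the growth factor Igf1 (4.76, SE 0.55) and the urokinase receptor Plaur (4.56, SE 0.49). The largest falls were Gp9 (−3.44, SE 0.47), Gpr165 (−3.39, SE 0.47), Ccr1 (−2.73, SE 0.45), the flagellin receptor Tlr5 (−2.73, SE 0.37), Hpgd (−2.59, SE 0.43), the ephrin ligand Efnb2 (−2.41, SE 0.34), Trp53i11 (−2.37, SE 0.57) and the collagen gene Col27a1 (−2.35, SE 0.40). Trp53i11 missed the threshold without KO PBS replicate 2 (adjusted p = 0.0704) or replicate 3 (adjusted p = 0.0877). Leaving out KO PBS replicate 2 gave 760 and 356 genes, KO PBS replicate 3 gave 770 and 343, and WT PBS replicate c gave 418 lower genes. The authors' deposited table listed 3305 genes with an adjusted p under 0.05, of which 1819 were called here in the same direction.

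In the PBS comparison 5 lists passed with either correlation. The disease-associated list had 31 of 40 higher (34 adjusted over the list alone; adjusted p = 0.00159 with an estimated correlation) and the interferon response 21 of 28 (25 adjusted over the list alone; adjusted p = 0.0177 with an estimated correlation), with Lgals3bp at 534 ± 75.9 against 79.9 ± 8.25 CPM. Cholesterol synthesis had 6 of 25 higher (7 adjusted over the list alone; adjusted p = 0.0127 with an estimated correlation), with Srebf2 (0.99, SE 0.19) and the sterol carrier Stard4 (2.34, SE 0.53). Glycolysis had 11 of 18 higher (14 adjusted over the list alone; adjusted p = 0.0215 with an estimated correlation) and proliferation 7 of 28 (8 adjusted over the list alone; adjusted p = 0.0177 with an estimated correlation). Lysosomal genes rose in 29 of 49 (30 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.87e-22, adjusted p = 0.0916 with an estimated correlation) and ribosomal protein genes in 35 of 39 (37 adjusted over the list alone; camera adjusted p = 4.52e-24, adjusted p = 0.116 with an estimated correlation). Homeostatic genes fell in 13 of 34 and rose in 2 (16 and 2 adjusted over the list alone; camera adjusted p = 2e-06, adjusted p = 0.209 with an estimated correlation); Selplg (−1.28) fell and Gas6, a ligand of Axl, rose by 1.19. Il1b (2.38, SE 0.29), H2-K1 (2.40, SE 0.18), C3ar1 (1.31, SE 0.14), Mbp (2.45, SE 0.31) and Cd22 (4.07, SE 0.26) were again higher. By camera with the preset correlation 15 lists rose and 2 fell. By fry 16 rose and 1 fell.

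**Figure D3:**
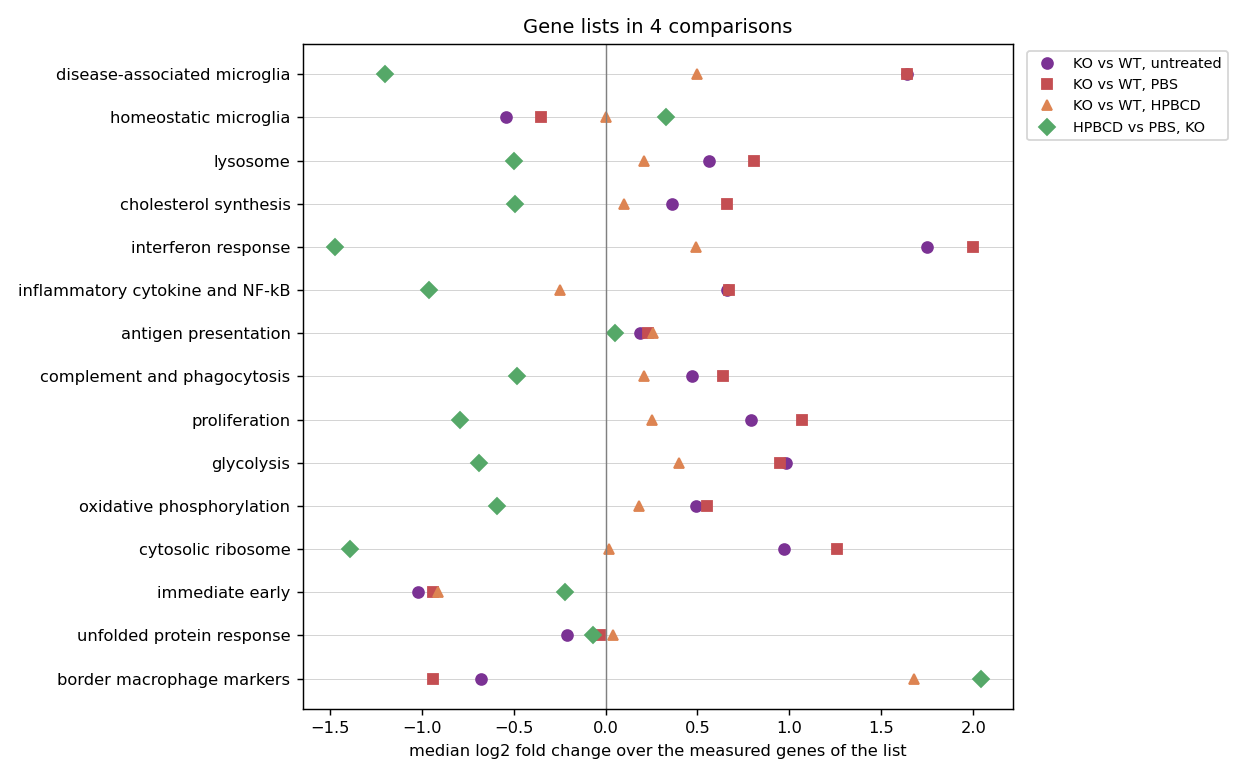
Median log2 fold change (horizontal axis) over the measured genes of 15 lists fixed before the data were examined, in 4 comparisons marked by colour and shape. For the disease-associated list the medians were 1.64 and 1.64 for KO against WT without treatment and with PBS, 0.50 with HPBCD, and −1.20 for HPBCD against PBS in KO.

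The genes called between untreated KO and WT were then followed in the treated libraries, which shared the filter and the spread of the fit that called them. The 1788 genes higher in untreated KO had a median log2 difference of 0.93 between KO and WT with PBS. This passed limma's fry test at 0.05, and 1013 of them were called higher there, against 125.3 for lists drawn independently. The 1621 lower genes had a median of −0.50, which passed as well, with 601 called lower against 67.8 for independent lists. With HPBCD the medians between KO and WT were 0.20 for the higher genes, which passed fry, and 0.04 for the lower genes, which did not. The sign of the median of 0.04 differed between settings, down to −0.06 with limma voom. The signature was also taken from the untreated libraries alone and tested in the libraries of each comparison alone. Its medians for higher and lower genes were then 1.08 and −0.60 with PBS, 0.17 and −0.06 with HPBCD, and −0.87 and 0.49 for HPBCD against PBS in KO, and each but −0.06 passed fry. Without untreated KO replicate 5 and WT HPBCD replicate 3 the median of the higher genes was 0.12 and did not pass. The difference between KO and WT was nearer to 0 with HPBCD than with PBS for 88.1% of the higher and 91.9% of the lower genes.

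**Figure D4:**
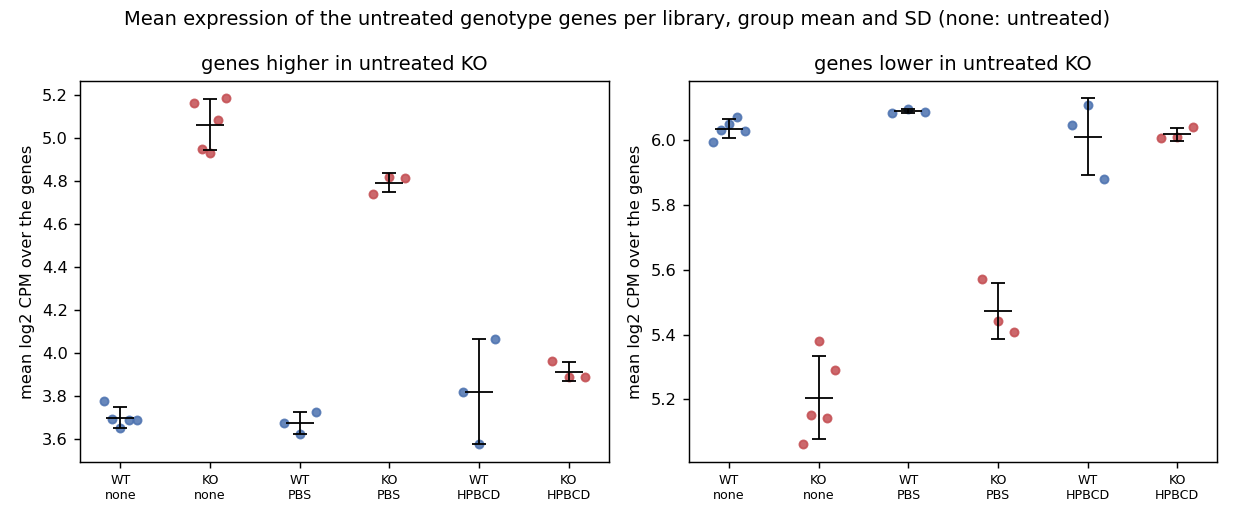
Mean log2 CPM per library (points) over the 1788 genes higher and the 1621 genes lower in untreated KO, by group, with group mean and SD in black. The higher genes averaged 4.79 in KO with PBS and 3.91 in KO with HPBCD, against 3.67 and 3.82 in WT, and the lower genes 5.47 and 6.02 against 6.09 and 6.01. WT HPBCD replicate 3, with counts on many genes, moved the WT HPBCD means. Its higher genes stood at 4.07, against 3.82 and 3.57 in WT HPBCD replicates 1 and 2. Its lower genes stood at 5.88, against 6.05 and 6.11.

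The next comparison asks what HPBCD changed in KO microglia, against PBS. Of the genes named above, Axl fell from 451 ± 69.8 to 94.3 ± 11.2 CPM (SD, n = 3; −2.32, SE 0.22, adjusted p = 1.18e-07), Apoe from 31960 ± 7260 to 8798 ± 560 CPM (−1.92, SE 0.22, adjusted p = 1.3e-06) and Itgax by 1.84 on the log2 scale. Of the disease-associated list 30 of 40 fell and 0 rose (33 fell adjusted over the list alone; camera adjusted p = 8.44e-32, adjusted p = 0.00608 with an estimated correlation). Homeostatic genes rose in 10 of 34 and fell in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 1.44e-08, adjusted p = 0.165 with an estimated correlation), with Selplg up by 1.04. In all 495 genes were higher and 754 lower by edgeR on all libraries. The counts were 824 and 1098 with the DESeq2 Wald test, 2307 and 2511 with limma voom, and 1954 and 2317 with only the 6 libraries compared. The largest rises were Gp9 (3.16, SE 0.47), Gpr165 from 20.7 ± 17.7 to 179 ± 17.8 CPM (3.04, SE 0.46), Tlr5 (2.68, SE 0.37), Kcnrg (2.13), Col27a1 (1.97, SE 0.40), Hpgd (1.94), the cytoskeletal gene Nav3 (1.90, SE 0.27) and the guidance molecule Sema6d (1.87, SE 0.36). The largest falls were Gfap (−4.47, SE 0.96), C77080 (−3.59), Chst2 (−3.57, SE 0.42), Cst7 (−3.57, SE 0.49), Hpse (−3.54, SE 0.57), the phosphodiesterase Pde2a (−3.37, SE 0.33), Gpx3 (−3.25, SE 0.66) and Lox (−2.94). Kcnrg, Hpgd, C77080 and Lox missed the threshold without KO PBS replicate 2 (adjusted p = 0.053, 0.0516, 0.0603 and 0.0565) or replicate 3 (0.0502, 0.0683, 0.0617 and 0.0532). Without KO HPBCD replicates 1, 2 or 3 so did C77080 (0.082, 0.0722 and 0.0973) and Lox (0.0776, 0.0659 and 0.0979). Gfap missed it without KO HPBCD replicate 2 (adjusted p = 0.0621) or 3 (0.061), and Gpx3 without KO HPBCD replicate 3 (0.0513).

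By camera 14 lists were lower and 2 higher with HPBCD in KO, and 5 passed with an estimated correlation. By fry 11 were lower and 2 higher. Interferon response genes fell in 11 of 28 (21 adjusted over the list alone; camera adjusted p = 1.58e-16, adjusted p = 0.045 with an estimated correlation), with Lgals3bp at −2.11 (SE 0.20), Ifi44 at −1.79 and Rtp4 at −2.15. Inflammatory cytokine and NF-kB genes fell in 9 of 32 (12 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation), with Il1b at −2 (SE 0.29) and Cxcl16 at −1.20. Cholesterol synthesis fell in 3 of 25 (3 adjusted over the list alone; adjusted p = 0.0334 with an estimated correlation), among them Srebf2 (−0.94) and Insig1 (−1.35), the latter of which missed the threshold without KO PBS replicate 2 (adjusted p = 0.108). Proliferation fell in 6 of 28 (7 adjusted over the list alone; adjusted p = 0.045 with an estimated correlation), including Mcm6 (−1.64) and Hmgb2 (−0.82). Lysosomal genes fell in 23 of 49 and rose in 1 (29 and 1 adjusted over the list alone; camera adjusted p = 6.96e-16, adjusted p = 0.165 with an estimated correlation), with Ctsb at −1.37 and Lamp1 at −1.05. Ribosomal protein genes fell in 37 of 39 (37 adjusted over the list alone; camera adjusted p = 1.96e-33, adjusted p = 0.0862 with an estimated correlation), Rpl3 from 457 ± 46.3 to 190 ± 3.34 CPM (−1.33, SE 0.20). Glycolysis fell in 8 of 18 (10 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation) and oxidative phosphorylation in 6 of 33 (12 adjusted over the list alone; adjusted p = 0.294 with an estimated correlation). H2-K1 fell from 299 ± 62.7 to 68.8 ± 5.30 CPM (−2.18, SE 0.18, adjusted p = 8.29e-09), the smallest adjusted p of this comparison. The antigen presentation list counted 5 of 18 lower (5 adjusted over the list alone; camera adjusted p = 0.0439, adjusted p = 0.459 with an estimated correlation) with a median of 0.05 and a mean of −0.22, so median and test differ in sign. That list missed the threshold without KO PBS replicate 3 (adjusted p = 0.111). Among markers of other cells Mbp fell by 1.90 (SE 0.31). Border macrophage markers had 0 of 11 called by edgeR (3 higher adjusted over the list alone) while their list rose by camera (median 2.04, adjusted p = 0.000258, adjusted p = 0.255 with an estimated correlation).

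As a set, the 1788 genes higher in untreated KO had a median of −0.76 in KO with HPBCD against PBS, which passed fry, and 683 of them were called lower. The 1621 lower genes had a median of 0.46, which passed as well, and 434 were called higher and 1 lower. Npc1 itself did not pass in KO (0.55, SE 0.20, adjusted p = 0.0895). The authors' deposited table gave Npc1 a log2 fold change of 0.98 there (its adjusted p = 1.33e-06). The counts of 495 and 754 called genes became 155 and 445 without KO PBS replicate 2, 175 and 401 without KO PBS replicate 3, 264 and 437 without KO HPBCD replicate 1, 248 and 398 without KO HPBCD replicate 2, and 221 and 403 without KO HPBCD replicate 3. Of 4550 genes with an adjusted p under 0.05 in the authors' deposited table, 1209 were called here in the same direction.

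In WT microglia no gene passed between HPBCD and PBS. Npc1 stood at 273 ± 84.1 CPM with PBS and 426 ± 24.9 CPM with HPBCD (SD, n = 3; 0.57, SE 0.19, adjusted p = 1). Axl was at 42.0 ± 10.8 and 44.5 ± 16 CPM, Apoe at 4012 ± 877 and 4242 ± 701 CPM, and Tmem119 at 1704 ± 181 and 1690 ± 114 CPM. By edgeR 0 genes were higher and 0 lower, with 310 at an unadjusted p under 0.05. That is 1.82% of the genes tested, below the share of 0.05 that chance gives. The test may thus have been too strict here, and 0 calls do not show that HPBCD left WT microglia unchanged. Recovery of changed genes was not simulated for this comparison. The DESeq2 Wald test called 0 and 0 and limma voom 1 and 0. Genes with the untreated KO signature had medians of −0.01 for the higher and −0.08 for the lower genes, and neither passed fry. Of the 26 lists 0 were higher and 0 lower by fry. By camera, T and NK cell markers (median 2) and neutrophil markers (median 1.26) were higher and ribosomal protein (median −0.16) and oxidative phosphorylation genes (median −0.19) lower, and none of these 4 lists passed with an estimated correlation (adjusted p = 0.308, 0.308, 0.84 and 0.83). WT HPBCD replicate 3 is in this group, and without it the ribosomal and oxidative phosphorylation lists no longer passed (adjusted p = 0.981 and 0.186), nor did they without WT PBS replicate a (0.163 for oxidative phosphorylation and higher for the ribosomal list). The T and NK list did not pass without WT HPBCD replicate 1 (0.119), nor the neutrophil list without that library (0.672) or WT PBS replicates a or b (0.202 and 0.303). Of 1028 genes listed in the authors' deposited table, 209 had an adjusted p under 0.05, and 138 of the 209 had the sign of the counts.

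Whether HPBCD acted differently in KO and WT was tested directly as a difference of differences. The response was more negative in KO for Gfap (−6.42, SE 1.36, adjusted p = 0.0245), Hpse (−4.62, SE 0.91, adjusted p = 0.0131), Cst7 (−4.35, SE 0.70, adjusted p = 0.00256), Chst2 (−3.69, SE 0.59, adjusted p = 0.00281) and Pde2a (−3.33, SE 0.44, adjusted p = 8.15e-05). It was more positive in KO for Gp9 (3.29, SE 0.62, adjusted p = 0.00436), Gpr165 (2.84, SE 0.61, adjusted p = 0.0263), Tlr5 (2.51, SE 0.49, adjusted p = 0.00615), Col27a1 (2.22, SE 0.55, adjusted p = 0.0466) and the cilium-associated gene Cfap74 (2.01, SE 0.34, adjusted p = 0.00256). For Gfap, Hpse and Cst7 the fall in KO given above was smaller than this difference, so part of it came from a rise in WT. Cst7 was near the floor in WT, at 0.535 to 1.65 CPM with PBS and 1.26 to 3.22 CPM with HPBCD. Of 40 disease-associated genes 19 were lower in this contrast (28 adjusted over the list alone; camera adjusted p = 1.27e-25, adjusted p = 0.016 with an estimated correlation), as were 2 of 25 cholesterol synthesis genes (4 adjusted over the list alone; adjusted p = 0.0463 with an estimated correlation). In all 145 genes were higher and 186 lower by edgeR on all libraries. The counts were 297 and 551 with the DESeq2 Wald test, 953 and 928 with limma voom, and 990 and 860 with only the libraries of these 4 groups. Without WT HPBCD replicate 3 and untreated KO replicate 5, 63 were higher and 240 lower. Gpr165, Col27a1, Gfap and Hpse lost their calls in 11, 11, 7 and 5 of the 12 refits that left out a single library. The 2 counts became 87 and 133 without WT PBS replicate a, 98 and 115 without b, 47 and 112 without c, 23 and 73 without KO PBS replicate 2, 29 and 74 without KO PBS replicate 3, and 58 and 86 without WT HPBCD replicate 1. They became 39 and 74 without KO HPBCD replicate 1, 52 and 80 without KO HPBCD replicate 2, and 37 and 71 without KO HPBCD replicate 3. Without WT HPBCD replicate 3, 40 genes were higher.

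With HPBCD in both genotypes, 20 genes were higher in KO than in WT and 1, Npc1, was lower. Those that rose included Lrguk (1.79, SE 0.28, adjusted p = 0.0025), the immune receptor Ly9 (1.61, SE 0.25, adjusted p = 0.00263), Cd22 at 14.5 ± 1.70 against 5.43 ± 2.27 CPM (SD, n = 3; 1.55, SE 0.24, adjusted p = 0.00249) and S1pr1, a receptor for a sphingosine phosphate (1.56, SE 0.26, adjusted p = 0.00414). Sash1 (1.93, SE 0.33), Spp1, also called osteopontin (1.70, SE 0.34), Nrp1 (1.47, SE 0.30) and Anxa5 (1.29, SE 0.24) completed the largest rises. Apoe stood at 8798 ± 560 against 4242 ± 701 CPM (1.14, SE 0.21, adjusted p = 0.0126), Axl rose by 1.17 (SE 0.21) and Cd63 by 0.98 (SE 0.20), and with Spp1 these made 4 of 40 disease-associated genes higher (22 adjusted over the list alone; camera adjusted p = 2.68e-22, adjusted p = 0.0294 with an estimated correlation). By camera 10 lists were higher and 4 lower, and 1, the disease-associated list, passed with an estimated correlation. By fry 1 list was higher and 0 lower. Homeostatic genes had 0 called (1 adjusted over the list alone, median 0.00, camera adjusted p = 0.499). In this comparison 1520 genes (8.95% of those tested) had an unadjusted p under 0.05. Other fits called more genes and a different balance: 43 higher and 99 lower with the DESeq2 Wald test, 430 and 670 with limma voom, and 96 and 86 with edgeR on only these 6 libraries. A term for the share of male RNA gave 18 and 1. By edgeR on all libraries the higher count was 5 without WT HPBCD replicate 3, 6 without WT HPBCD replicate 2, and 7, 12 and 7 without KO HPBCD replicates 1, 2 and 3. Without WT HPBCD replicate 3 adjusted p was 0.302 for Apoe, Axl, Spp1 and Anxa5, 0.515 for Cd63, 0.523 for Nrp1 and 0.0916 for S1pr1, and without both libraries with counts on many genes 1 gene was higher. Over the refits without 1 library of these groups the highest adjusted p was 0.115 for Sash1, without WT HPBCD replicate 2, and Lrguk, Ly9 and Cd22 passed in each. The authors' deposited table listed 35 genes with an adjusted p under 0.05. For 0 of the 35 did its sign match the counts as KO over WT, so it was read as WT over KO, and 8 of them were then called here in the same direction. The test of the difference with HPBCD minus that with PBS is the difference of differences above.

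PBS was set against no treatment in each genotype as a check of the vehicle, across sheets counted separately, so a vehicle effect and a difference between sheets cannot be told apart. In KO, Axl was at 435 ± 25.7 CPM untreated (SD, n = 5) and 451 ± 69.8 CPM with PBS (n = 3), and Apoe at 30790 ± 5350 and 31960 ± 7260 CPM. Npc1 in WT was at 434 ± 31.7 CPM untreated and 273 ± 84.1 CPM with PBS (−0.73, SE 0.18, adjusted p = 0.24), and missed the threshold with all libraries but passed without untreated WT replicate 4 (adjusted p = 0.0393) or WT PBS replicate c (adjusted p = 0.0281). In KO edgeR called 0 higher and 0 lower genes, with 1300 (7.65% of the genes tested) at an unadjusted p under 0.05. The DESeq2 Wald test called 10 and 53 there, and limma voom 0 and 1. In WT edgeR called 0 and 0, with 1907 (11.22%) at an unadjusted p under 0.05. The DESeq2 Wald test called 147 and 192 there, and limma voom 1 and 2. Leaving out untreated WT replicate 4 gave 153 higher and 93 lower genes in WT, and leaving out WT PBS replicate c gave 1 and 7. Leaving out untreated KO replicate 4 or KO PBS replicate 3 gave 1 higher gene in KO, and untreated KO replicate 5 gave 1 and 1. By camera 12 lists were lower with PBS in KO and 16 in WT, led in WT by the lysosome (median −0.36) and disease-associated lists (median −0.50). With an estimated correlation 0 passed (adjusted p = 0.178 and 0.0857 for these). By fry 0 lists were higher and 0 lower in KO, and 0 higher and 3 lower in WT. Of the untreated KO signature, the higher and lower genes had medians of −0.17 and 0.20 for PBS against no treatment in KO, which both passed fry, and −0.16 and 0.03 in WT, which did not. The untreated libraries chose these genes, so the selection alone moves such medians toward WT in KO. The authors' deposited tables listed 21 genes for KO and 325 for WT with an adjusted p under 0.05. Npc1 was among those for WT, at −0.7 (adjusted p = 0.0141 in that table).

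Whether the genotype difference itself differed between PBS and no treatment was tested last. Hpse differed between genotypes by 7.05 with PBS and 4.55 without treatment, and Axl by 3.50 and 2.73. By edgeR 0 genes were higher and 0 lower, with 847 at an unadjusted p under 0.05. That is 4.98% of the genes tested, near the share of 0.05 that chance gives. The DESeq2 Wald test called 2 and 27 and limma voom 1 and 0. Npc1 had a difference of 1.24 (SE 0.25, adjusted p = 0.401), which passed without WT PBS replicate c (1.5, adjusted p = 0.00971), and that refit called 1 higher gene. By camera 8 lists were higher, the lysosome (median 0.26) and homeostatic lists (median 0.24) among them, and 1 lower. With an estimated correlation 0 passed (adjusted p = 0.643 for these 2). By fry 0 lists were higher and 0 lower. The signature genes higher in untreated KO had a median of 0.01, which did not pass fry, and the lower genes 0.15, which did, but the untreated libraries that chose them enter this contrast as well.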

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

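Of the tests of explanations below, those of sequencing depth, receptor genes, exon length, oligodendrocytes, astrocytes, background in the oligodendrocyte genes and library scaling were chosen only after the result was seen.

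Genes that answered HPBCD differently in KO and WT were singled out because the difference itself passed a test. The interaction called 145 genes higher and 186 lower. Gp9 (3.29), Gpr165 (2.84), Tlr5 (2.51), Col27a1 (2.22) and Cfap74 (2.01) had the more positive response in KO. Gfap (−6.42), Hpse (−4.62), Cst7 (−4.35), Chst2 (−3.69) and Pde2a (−3.33) had the more negative response in KO. For Gfap, Hpse and Cst7 part of the difference came from a rise in WT. Gpr165 and Col27a1 missed the threshold in 11 of the 12 refits without 1 library, with adjusted p up to 0.0951 without KO PBS replicate 3 and 0.167 without that library. Gfap reached 0.0839 without KO HPBCD replicate 2, and Hpse 0.0625 without KO PBS replicate 2.

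Single libraries far from the other 4 of their group were found in 9 of 98 group tests, and chance gives about 1 in 20. In untreated KO, Gpr165 was 2.82 log2 CPM in replicate 1 (others 4.28 to 4.45), Atp8b1 was −0.99 in replicate 4 (others 1.72 to 2.64) and Trp53i11 was −1.4 in replicate 2 (others 1.69 to 2.82). In untreated WT, Gpx3 was −1.64 in replicate 5 (others 1.39 to 2.41) and Cass4 was 6.54 in replicate 3 (others 5.75 to 5.94). The mean of the immediate early genes was 6.47 log2 CPM in untreated WT replicate 2 (others 7.16 to 7.38). Rn45s, a ribosomal RNA precursor, took 8.79% of the counts in untreated KO replicate 1 (others 5.82% to 6.24%). Untreated KO replicate 5 had a total of 18.6 × 10⁶ counts (others 26.89 to 29.49 × 10⁶) and at least 10 counts on 18882 genes (others 12650 to 14161).

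That last library and WT HPBCD replicate 3 held counts on many more genes than the other 20. Depth is argued against, since the higher of their totals, 23.81 × 10⁶, lay below the lowest other, 24.28 × 10⁶. RNA of other brain cells is argued against as well, since odorant and vomeronasal receptor genes had counts for 929 and 1384 of 1456 members, against at most 332 elsewhere. Fragments spread over the genome by length may account for it, as counts on 6650 otherwise silent genes went with exon length (Spearman correlation across genes 0.404 and 0.517, genes not being independent replicates). Whether these came from genomic DNA stays open, because the ratio of X to autosomal counts was 0 in untreated KO replicate 5 and cannot be read. In WT HPBCD replicate 3 the ratio was 0.433 (7.48 against 17.3 counts per kb). That library held both Xist and Y-linked counts, and the test was not set for it, so its ratio decides nothing. Beyond RNA of other brain cells, no biological explanation was tested.

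Oligodendrocyte and astrocyte genes such as Mbp, Mobp and Gfap were higher in KO, and Mbp and Gfap were lower with HPBCD. Whole oligodendrocytes among the sorted cells are argued against, since with PBS the 14 other listed genes in the count table, those too low to be tested included, together changed by 14.7% of the Mbp change (upper limit 19.3%). For whole astrocytes the same share was −33.3% of the Gfap change (upper limit 419.3%), too wide to decide. Background of the 2 libraries above is argued against as the only source for the called genes, whose median was 2.61 without both and 2.79 with them. Of the 2, only untreated KO replicate 5 is in that comparison, and genes raised in it alone would rarely be called. Mbp was 480 CPM in that library and 211 to 297 CPM in the other untreated KO libraries, so a part from background stays open. Taken up myelin or process RNA may be a source and was not tested.

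The border macrophage list was higher with HPBCD in KO by camera (adjusted p = 0.000258) but did not pass with an estimated correlation (adjusted p = 0.255), and edgeR called 0 of its 11 genes. Mrc1 went from 54.5 ± 16.3 to 154 ± 21.9 CPM (SD, n = 3). Across KO libraries it was 44.9 to 92.2 CPM untreated or with PBS, and 133 to 177 CPM with HPBCD, without overlap. WT libraries without HPBCD varied widely for Mrc1. It was 17.9 CPM in WT PBS replicate b, 150 CPM in WT PBS replicate c and 161 CPM in untreated WT replicate 4. Levels near the mean of KO with HPBCD thus also occurred in WT without HPBCD. A changed share of border macrophages among the sorted cells may account for it, since deviations from group means correlated at 0.434 on average, against 0.098 at the 95% point of 10000 random lists. DESeq2 size factors moved the median of all genes by only 0.001 here, so the list medians of 2.05 with them and 2.04 with TMM decide nothing about library scaling. A scaling factor moves all genes alike, however, and the median of all genes was −0.014 in this comparison. That argues against scaling as the source of the list median. Whether such a change of share arose in the tissue or in the sort was not tested, and neither was a change of these genes within microglia.

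Other splits of the same libraries were fitted for each comparison. For untreated KO against WT 1 of 100 splits, the real one, called as many genes (3409, highest other 1401). Chance is thus unlikely there, provided that the libraries came from separate animals, which the labels do not say. The highest other put untreated KO replicates 1 to 4 with untreated WT replicate 5. Splits of 3 against 3 number 10, too few for a share under 0.05: the real and the highest other counts were 1902 and 0 for genotype with PBS, 21 and 0 for genotype with HPBCD, 1249 and 0 for HPBCD in KO, and 0 and 3 for HPBCD in WT, where every split reaches a real count of 0. The same holds for the untreated KO signature. Real and highest other medians for its higher genes were 0.93 and 0.38 with PBS, 0.20 and −0.18 with HPBCD, and −0.76 and 0.33 for HPBCD in KO. For its lower genes they were −0.50 and 0.22, 0.04 and −0.11, and 0.46 and −0.21.

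For the interaction 10 of 100 splits called as many genes as the real one (331, highest other 1187), so chance cannot be excluded by them. All 10 kept the PBS genotypes apart, and splits that mixed them called at most 7. A split with several times the real count points to a structure of the samples, here the genotype difference with PBS. For PBS against no treatment the real count was 0, which all 56 of 56 splits reach whatever the data, so their number says nothing about chance. The highest other counts were 563 in KO, with untreated KO replicates 1, 2 and 4 together, and 1706 in WT, with untreated WT replicates 1, 3 and 5 together. Those 3 WT libraries held 6.83% to 9.35% of counts on Rn45s and the other 2 held 4.04% to 4.99%, so the untreated WT libraries have a structure of their own. For the genotype difference with PBS minus that without treatment, the real count was 0 as well, so 100 of 100 splits reach it and nothing follows about chance. The highest other, 2898, kept the KO PBS libraries together.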

How the results depend on the processing

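The setting that left out both libraries with counts on many genes was chosen after seeing the data. The cause of the changes below was not tested.

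DESeq2 size factors gave 13 genes higher for genotype with HPBCD. The DESeq2 Wald test gave 1135 lower for genotype with PBS, 43 and 99 (higher and lower) for genotype with HPBCD, 824 higher for HPBCD in KO, 10 and 53 for PBS in KO, 147 and 192 for PBS in WT, 297 and 551 for the interaction, and 2 and 27 for the genotype difference with PBS minus untreated. Limma voom gave 2104 and 1737, 430 and 670, 2307 and 2511 for the first 3 of these comparisons, 1 higher for HPBCD in WT, 1 lower for PBS in KO, 1 and 2 for PBS in WT, 953 and 928 for the interaction, and 1 higher for the last. Without a filter 1 gene was lower for PBS in KO. With only genes of at least 10 CPM 383 were lower for the interaction. With only the libraries compared the counts were 986 lower for untreated genotype, 1840 and 1347 for genotype with PBS, 96 and 86 with HPBCD, 1954 and 2317 for HPBCD in KO, 1 lower for PBS in KO, and 990 and 860 for the interaction. Without both libraries 1 gene was higher for genotype with HPBCD, 1 higher and 1 lower for PBS in KO, 1 lower for PBS in WT, and 63 higher for the interaction, and the higher signature genes had 0.12 with HPBCD and did not pass.

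The lower signature genes had a median of 0.04 for genotype with HPBCD. It was −0.04 with DESeq2 size factors and the Wald test, −0.06 with voom, with the CPM filter and with only the libraries compared, −0.02 with the replicate block and −0.05 without both libraries. The other 5 signature medians kept their sign in each setting run.

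Leaving out 1 library at a time gave 1533 to 1900 higher and 1386 to 1876 lower genes for untreated genotype, 760 to 1018 and 343 to 574 with PBS, and 5 to 19 and 1 to 1 with HPBCD. It gave 155 to 394 and 398 to 632 for HPBCD in KO and 23 to 170 and 71 to 189 for the interaction. For HPBCD in WT it gave 0 to 0 and 0 to 0 by edgeR (with all libraries 310 genes, 1.82%, had an unadjusted p under 0.05). For PBS it gave 0 to 1 and 0 to 1 in KO and 0 to 153 and 0 to 93 in WT, and 0 to 1 and 0 to 0 for the genotype difference. Signature medians ran from −0.85 to −0.67 and 0.38 to 0.51 for HPBCD in KO, 0.83 to 1 and −0.57 to −0.48 for genotype with PBS, and 0.14 to 0.31 and −0.06 to 0.11 with HPBCD (−0.06 without WT HPBCD replicate 3).

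Of 270 named gene and 84 gene list results 0 of those called changed sign, but calls were lost. Of the 84 list results an estimated correlation ended the call of 70, leaving out both libraries of 9, leaving out shared members of 7, size factors of 2 and the replicate block of 1 of 47. Leaving out 1 library ended the call in 52 of 668 refitted list values, and in 210 of 2076 refitted values of named genes, with 3 calls made. Of the named gene results, calls ended in 17 without both libraries, 9 with only the libraries compared (1 made), 9 without a filter, 8 of 177 with the block, 8 with voom (4 made), 6 with size factors, 5 with a term for male RNA, 3 of 243 with the CPM filter and 1 with the Wald test (3 made). Of 32 pairs of libraries with the same replicate number, 4 had deviations from group means correlated above 0.1 (−0.204 to 0.249). Pairs with different numbers were not set beside them, so pairing by number is not excluded. With the number as a block 422 and 733 genes were called for HPBCD in KO. No paired analysis was possible with WT PBS because its libraries carry no number.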

Other observations

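The gene families below were chosen only after the data were seen, as 186 groups of genes sharing a symbol stem, with at least 10 tested genes outside the fixed lists.

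Annexins, which bind membranes in the presence of calcium, rose in untreated KO in 7 of 10 genes (median 1.33; camera adjusted p = 7.92e-07, adjusted p = 0.11 with an estimated correlation). Anxa5, which binds phosphatidylserine, went from 15.4 ± 2.05 to 119 ± 23 CPM (SD, n = 5), and Anxa4 and Anxa11 rose by 1.95 and 1.56 on the log2 scale. With PBS 7 of 10 were again higher in KO (median 1.46; adjusted p = 1.09e-08, adjusted p = 0.0742 with an estimated correlation). With HPBCD against PBS in KO 6 of 10 fell (median −1.10; adjusted p = 1.3e-06, adjusted p = 0.164 with an estimated correlation).

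Toll-like receptors outside the fixed lists fell in untreated KO in 7 of 11 genes (median −0.56; camera adjusted p = 0.00184, adjusted p = 0.1 with an estimated correlation). Tlr5 went from 22.9 ± 2.24 to 4.96 ± 2.17 CPM (SD, n = 5), and Tlr3 and Tlr4 fell by 0.82 and 0.80 on the log2 scale, while Tlr7 (−0.17) and Tlr1 (−0.26) were not called. With PBS, Tlr5 was at 23.4 ± 10.4 CPM in WT and 3.33 ± 1.67 CPM in KO (SD, n = 3). Tlr3 was at 66.8 ± 4.62 and 35.3 ± 5.6 CPM, and Tlr4 at 126 ± 40.3 and 68 ± 11.6 CPM. Tlr7 was at 335 ± 118 and 306 ± 57.1 CPM, and Tlr1 at 58.9 ± 8.35 and 67.3 ± 14.2 CPM. In KO 3 of 11 rose with HPBCD against PBS (median 0.72; adjusted p = 0.00829, adjusted p = 0.164 with an estimated correlation).

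Zinc finger genes with the stem Zfp fell in untreated KO in 91 of 354 and rose in 10 (median −0.34; camera adjusted p = 3.22e-08, adjusted p = 0.378 with an estimated correlation). In KO 20 rose and 0 fell with HPBCD against PBS by edgeR (median 0.26; adjusted p = 1.41e-06, adjusted p = 0.569 with an estimated correlation), a comparison with 3210 genes at an unadjusted p under 0.05.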
